A study of Mus musculus with 19 samples.

How the data were processed

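The data were Tn5 insertion levels in 87697 consensus peaks for 19 ATAC-seq libraries of sorted mouse tumor cells, in 6 groups formed from the cell line and genotype labels. Per the submitters' processing notes, cutadapt, Bowtie2, MACS2 and DESeq2 were used with the mm10 genome, and no versions are given in the sources used here. Library construction followed a published ATAC-seq protocol, per the labels. The labels give total RNA as the molecule, although the titles and the peak matrix are those of ATAC-seq. How reads were shifted for the transposase, how peaks were merged and whether replicates were pooled for peak calling are not given in the sources used here.

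The deposited values are on a log2 scale, with the form of a variance-stabilising transformation of insertion counts, which flattens low levels towards a floor of 7.38. Inverting that transformation gave whole counts for 100.0% of values within a tolerance of 0.001, with a largest deviation of 4.0e-05. Median-of-ratios size factors computed from those counts differed from the factors in the deposited values by 0.0%. Normalised insertions are the recovered counts divided by these factors. Because the scale compresses low levels, a difference of 0.37 is a doubling from 72.9 normalised insertions, 0.46 from 128.8 and 0.61 from 286.6, which are the lower quartile, median and upper quartile of all values. Each peak name gave a start and end 749 apart, and coordinates are printed as in the file.

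Columns were matched to libraries by name. The columns of Res499 STAT1 KO carry other replicate numbers than the titles of those libraries, so they were matched as a group and their numbers are those of the columns. All columns were used. The 100 highest peaks held 1.47 to 1.75% of a library's insertions. Library totals of 17.14 to 36.62 M set the precision, and a count of 0 allows up to 3 insertions, which is 2.02 to 4.1 normalised insertions, depending on the library. Such floors cover counting error only. Replicates of each group were compared with a chi-square of their counts, whose value per degree of freedom was 2.15 to 6.21, so no pair agreed within sampling noise and none was merged.

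The groups, tests, gene lists, rule for named peaks and first set of alternatives were chosen before the data were examined. Every comparison used limma 3.58.1 in R 4.3.3 on the deposited values, with group means of all 19 libraries in 1 fit, moderated variances with a trend, two-sided tests and Benjamini-Hochberg adjustment over all peaks at 0.05. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures. Peaks were assigned to the nearest gene span within 50 kb from a RefSeq gene table of the GRCm38.p6 assembly, which is mm10, and 78607 peaks had such a gene. That table gives no strand, so the planned distance to a transcription start was replaced by distance to the gene span, and peaks within 1 kb of either gene end (15531) stand in for promoters. Exons were not annotated, so a peak inside a gene is given only as that. No genome sequence was used here, so motif tests and corrections for GC content were not run.

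The 18 gene lists covered interferon-stimulated genes, MHC class I and class II antigen presentation, nucleic acid sensing, inhibitory ligands, NF-kB and AP-1 genes, melanocyte pigmentation, dedifferentiated melanoma and neural crest, mesenchymal and matrix genes, hypoxia, cell cycle, housekeeping genes, and markers of T and NK cells, B cells, myeloid cells, endothelium and fibroblasts. They were tested with camera of limma at its preset correlation, adjusted over lists within a comparison. Over the 9 comparisons 28 list tests passed, and 5 passed with an estimated correlation. Named peaks were the 5 largest rises and falls on the deposited scale among passing peaks whose groups did not overlap (1 per gene, an unassigned peak counting as its own gene), the best peak (smallest p in that comparison) of each of 12 fixed genes, up to 3 genes of each other list that passed, and the gene-end peaks of Stat1 and Irf3. Ifit1 had no assigned peak, which left 11. Of the peaks called, 6398 had groups that did not overlap in Res499 against B16, 6792 in Res499 STAT1 KO, 3873 in B16 STAT1 KO, 4433 in IRF3 KO and 26522 in DKO. Called peaks were selected for a difference, so a chance share applies only to all peaks. Of all peaks, called or not, 19.8, 17.7, 34.4, 12.7 and 38.2% did not overlap, in the same order. Chance separates 5.71, 5.71, 20, 2.86 and 5.71% of peaks.

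Alternatives were quantile normalisation, centring each library on its median, leaving out peaks of low mean value, no variance trend, only the compared groups, a replicate block, leaving out each library, other list settings and other sets for the reversal. Added after the data were seen were voom on recovered counts, division by each library's median shift per 10 Mb region, thinning of counts to the smallest total, and DKO replicates 1 and 3, the closest pair, taken as 1 library. The procedure was tested on simulated counts for all 87697 peaks with 200 changed peaks and a dispersion of 0.0128. For 1.5-fold, 2-fold and 4-fold changes it recovered 49.3, 95.5 and 100% in Res499 against B16 (6 false calls), 50.7, 95.5 and 100% in Res499 STAT1 KO (14), 35.8, 85.1 and 100% in B16 STAT1 KO (8), 55.2, 95.5 and 100% in IRF3 KO (7) and 46.3, 91 and 100% in DKO (11). All simulated peaks and groups shared 1 dispersion and varied independently, without shifts over regions or a deviating library. These rates therefore check the procedure and do not give the rates in the data.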

Results

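Chromatin accessibility was measured by ATAC-seq, in which a transposase (Tn5) inserts sequencing adapters into open DNA, in sorted tumor cells of mouse melanoma lines. B16-F10 (B16 below) is a melanoma line, and Res499 is a line resistant to immune checkpoint blockade, the antibody therapy that releases inhibited T cells. The 19 libraries fell into 6 groups. B16 had 3 libraries of the WT genotype and 2 of STAT1 KO. Res499 had 4 WT, 3 STAT1 KO, 4 IRF3 KO and 3 DKO libraries, where KO is a knockout and the labels do not name the genes of the DKO. STAT1 is the transcription factor that carries interferon signals to DNA, and IRF3 is a factor that turns on interferon genes once foreign nucleic acid is sensed. Over 87697 peaks of the mm10 genome, the insertions totalled 24.42 to 27.61 M per library in B16 WT, 24.16 to 27.21 M in B16 STAT1 KO and 17.14 to 20.46 M in Res499 WT. They totalled 23 to 30.14 M in Res499 STAT1 KO, 21.71 to 36.62 M in IRF3 KO and 18.21 to 30.84 M in DKO. Levels are normalised insertions per peak, given as mean ± SD, with the number of libraries of each group as just listed. Differences ± SE are on the deposited variance-stabilised scale, where a doubling measures 0.37 from the lower quartile of all values, 0.46 from the median and 0.61 from the upper quartile. All adjusted p-values of single peaks come from limma with Benjamini-Hochberg adjustment. Nothing in the labels says that replicates came from separate cultures or animals, so these p-values measure the spread between the samples, which may be technical.

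The peak over the end of Stat1 (chromosome 1, 52119079 to 52119828) stood at 774, 835 and 814 normalised insertions in the B16 WT libraries and at 747 and 692 in B16 STAT1 KO. It stood at 771, 856, 690 and 822 in Res499 WT, at 649, 692 and 806 in Res499 STAT1 KO, at 748, 744, 809 and 778 in IRF3 KO and at 621, 706 and 674 in DKO. The STAT1 KO differences from WT were -0.10 ± 0.07 in Res499 (adjusted p = 0.386) and -0.12 ± 0.08 in B16 (adjusted p = 0.406). The peak over the end of Irf3 (chromosome 7, 44998380 to 44999129) stood at 325, 346 and 316 in B16 WT, at 251 and 267 in B16 STAT1 KO, at 302, 325, 282 and 269 in Res499 WT and at 235, 286 and 262 in Res499 STAT1 KO. It stood at 309, 265, 303 and 365 in IRF3 KO and at 216, 178 and 185 in DKO. It did not differ past the threshold in IRF3 KO (0.04 ± 0.06, adjusted p = 0.767) and was lower in DKO (-0.31 ± 0.06, adjusted p = 8.3e-05). For the Stat1 peak the DKO difference was -0.17 ± 0.07 (adjusted p = 0.0407), and it was 0.03 (adjusted p = 0.74) once the median shift of each 10 Mb region was divided out. Accessibility at a gene end does not show whether the coding sequence was deleted, so these values do not check the knockouts.

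Res499 was compared with B16, both WT, to ask how chromatin differs between the resistant and the parental line. The largest gains in Res499 lay at the end of A830018L16Rik (chromosome 1, 11413865 to 11414614), where 401 ± 24.6 normalised insertions stood against 23.3 ± 4.31 in B16, a 17.2-fold higher level (difference 1.52 ± 0.06, adjusted p = 6.5e-26), and inside Kctd3 (chromosome 1, 188975617 to 188976366), with 287 ± 43.5 against 20.2 ± 3.15 (14.2-fold). A peak at the end of Phyhipl (chromosome 10, 70599246 to 70599995) was 9.82-fold higher, and peaks inside Celf4, an RNA-binding splicing regulator, and Dars2, the mitochondrial aspartyl-tRNA synthetase, were 15.3-fold and 13.1-fold higher. The largest losses were a pair of neighbouring peaks on chromosome 4 with no gene within 50 kb (88941731 to 88942480, 117 ± 12.1 against 558 ± 29.9, 4.77-fold lower, and 88940521 to 88941270, 4.41-fold lower), a peak 6.8 kb from Mid1 (2.77-fold lower) and a peak inside Tafa5 (chromosome 15, 87715095 to 87715844, 2.78-fold lower). A Y-chromosome peak 2.2 kb from Gm52481 was 2.18-fold lower (difference -0.87 ± 0.08), and its call was lost once regional shifts were divided out (-0.21, adjusted p = 0.155).

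Between the lines, peaks of interferon-stimulated genes moved in both directions. Of 181 such peaks, 13 were higher in Res499, 8 were lower and 160 did not pass (14 and 8 when adjusted over the list alone). The list test gave adjusted p = 0.378. Among 11 genes fixed beforehand, 4 had a higher best peak. Tap1, a transporter that feeds peptides to MHC class I, stood at 662 ± 38.9 against 427 ± 73.6 (1.55-fold, adjusted p = 1.6e-05). Irf7, a factor that amplifies interferon production, stood at 435 ± 26.5 against 314 ± 15.8 (adjusted p = 0.00129). Cd274, which encodes the T cell inhibitor PD-L1, stood at 147 ± 24.6 against 95.2 ± 7.72 (adjusted p = 0.0176), and its call was lost without B16 WT replicate 1 (0.0926) or 2 (0.0776) or Res499 WT replicate 2 (0.0898). Oas1a, an antiviral enzyme, stood at 371 ± 55.2 against 285 ± 21.7 (adjusted p = 0.0438), and this call was lost without B16 WT replicate 1 (0.0803), 2 (0.224) or 4 (0.0855), without Res499 WT replicate 2 (0.136), 3 (0.0968) or 4 (0.129), with counts thinned to the smallest total (0.078) and with regional shifts divided out (0.115). Of 43 MHC class I peaks, 7 were higher and 36 did not pass (8 higher when adjusted over the list alone). The list missed the threshold (adjusted p = 0.0588) but passed without B16 WT replicate 1 (0.0111) and without Res499 WT replicate 1 (0.0497), 3 (0.0393) or 4 (0.0464), with quantile normalisation (0.0182) and with voom weights (0.0473). Of 88 peaks near T cell and NK cell marker genes, 7 were higher and 81 did not pass (7 higher when adjusted over the list alone). Its list test gave adjusted p = 0.0193, and adjusted p = 0.231 with an estimated correlation. The peaks that led this list lay 2.8 kb from Pdcd1, which encodes the inhibitory receptor PD-1 (227 ± 30.7 against 49.8 ± 10.2, 4.56-fold), 12.5 kb from Cd2 (2.02-fold) and at the end of Eomes, a T cell transcription factor (2.05-fold). Without B16 WT replicate 2 the adjusted p of this list was 0.062, with gene-end peaks it was 0.105 and with 1 mean per gene 0.126.

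In all, 6847 peaks differed between Res499 and B16, 3857 higher and 2990 lower in Res499, of which 686 were at least 2-fold higher and 163 at least 2-fold lower. Counts fell to 4017, 4083 and 4536 without B16 WT replicate 1, 2 and 4. With regional shifts divided out, 4710 of these peaks were still called in the same direction.

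**Figure D1:**
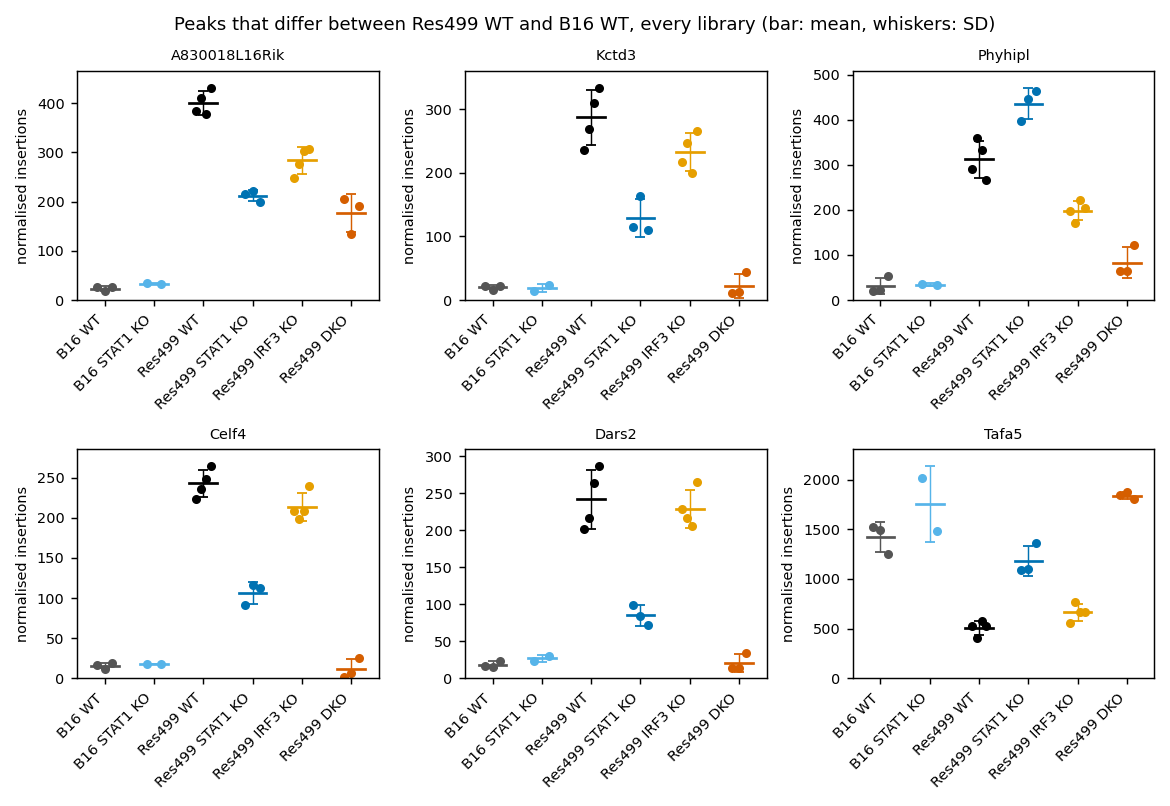
Normalised Tn5 insertions (vertical axes) per library, in the 6 groups named on the horizontal axes, for peaks that differed most between Res499 WT and B16 WT; points are libraries, horizontal bars are group means and whiskers are SDs. The A830018L16Rik peak stood at 401 in Res499 WT against 23.3 in B16 WT, and at 284 in IRF3 KO, 212 in Res499 STAT1 KO and 177 in DKO.

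STAT1 KO was compared with WT in Res499, to ask what the resistant line keeps without STAT1. Interferon-stimulated genes lost accessibility. At the end of Trim30a, an interferon-inducible TRIM protein gene (chromosome 7, 104464906 to 104465655), 67.8 ± 16.7 normalised insertions stood against 529 ± 56.1 in WT, a 7.8-fold lower level (-1.41 ± 0.07, adjusted p = 3.7e-23). Inside Ifi47, an interferon-inducible GTPase gene (chromosome 11, 49088102 to 49088851), the level was 6.75-fold lower (64.3 ± 8.9 against 434 ± 33.4), and at Trim12c and 1.3 kb from Rph3a it was 3.62-fold lower. A peak inside Ttc39b was 3.67-fold lower. The largest gains lay inside Klhl29 (563 ± 29.4 against 162 ± 20.2, 3.47-fold higher), Tafa5 (4-fold), the pentraxin gene Ptx3 (3.79-fold), Nr3c2, the mineralocorticoid receptor (3.97-fold), and Tcf7l1, a Wnt pathway transcription factor (2.17-fold).

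By group, 63 of the 181 peaks of interferon-stimulated genes, at 39 genes, were lower in Res499 STAT1 KO and 118 did not pass (75 lower when adjusted over the list alone). Camera gave this list adjusted p = 9.3e-24, and adjusted p = 0.00417 with an estimated correlation. Of the 11 fixed genes, 8 had a lower best peak, among them Oas1a (104 ± 28.9 against 371 ± 55.2, 3.58-fold, adjusted p = 2.5e-14), Isg15, a ubiquitin-like antiviral protein (82.3 ± 16.4 against 184 ± 11.7, adjusted p = 3.0e-06), Irf9, the DNA-binding partner of STAT1 and STAT2 (541 ± 85 against 786 ± 13.2, adjusted p = 8.9e-05), and Cd274 (81.4 ± 22.1 against 147 ± 24.6, adjusted p = 0.00107). Irf7 was 1.34-fold lower (adjusted p = 0.00382). Of MHC class II peaks, 20 of 39 were lower (24 when adjusted over the list alone; adjusted p = 1.9e-22, and adjusted p = 0.00835 with an estimated correlation), such as H2-DMb1, which helps load peptides (2.81-fold lower), and the class II chains H2-Aa (3.42-fold) and H2-Ab1 (2.32-fold). Of MHC class I peaks, 9 of 43 were lower and 2 higher (10 and 2 when adjusted over the list alone). For the list, adjusted p was 0.0111, but adjusted p = 0.325 with an estimated correlation, 0.126 with gene-end peaks and 0.0773 without STAT1 KO replicate 1. The leading peaks were at Tap2 (67.9 ± 16.8 against 288 ± 34.4, 4.25-fold lower), Tap1 (1.92-fold) and Nlrc5, the activator of class I genes (2.81-fold). B2m, the light chain of class I, stood at 1270 ± 182 against 1320 ± 117 (adjusted p = 0.716), and with quantile normalisation its difference was -0.16 (adjusted p = 0.0176). Of 71 nucleic acid sensing peaks, 13 were lower and 58 did not pass (13 lower and 1 higher when adjusted over the list alone; adjusted p = 0.00685, and adjusted p = 0.0748 with an estimated correlation), including those at the RNA sensor genes Dhx58 (1.9-fold) and Ifih1 (3.04-fold) and at Trim25 (1.87-fold). The Stat1 peak inside the gene (1.85-fold lower, adjusted p = 0.01) lost its call without STAT1 KO replicate 4 (0.0851). An Irf1 peak (1.36-fold lower, adjusted p = 0.0323) lost it without Res499 WT replicate 2 (0.0938), 3 (0.0532) or 4 (0.0549), without STAT1 KO replicate 1 (0.203) or 4 (0.103), with median centring (0.052), with regional shifts divided out (0.0668) and with thinned counts (0.0586). The Ifit3 peak (adjusted p = 0.126) passed without Res499 WT replicate 1 (0.0358).

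In Res499 STAT1 KO 7824 peaks differed from WT, 4427 higher and 3397 lower. At least 2-fold, however, 98 were higher and 408 lower. The share that was higher was 56.6%, and 67.4% with each library centred on its median. The count fell to 5174 without STAT1 KO replicate 2 and to 4315 without replicate 4. The myeloid marker list was not called (adjusted p = 0.184) but passed, higher, with regional shifts divided out (0.0359) and without STAT1 KO replicate 4 (0.00671). The fibroblast marker list (adjusted p = 0.184) passed, higher, with quantile normalisation (0.0246) and without that replicate (0.00831).

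**Figure D2:**
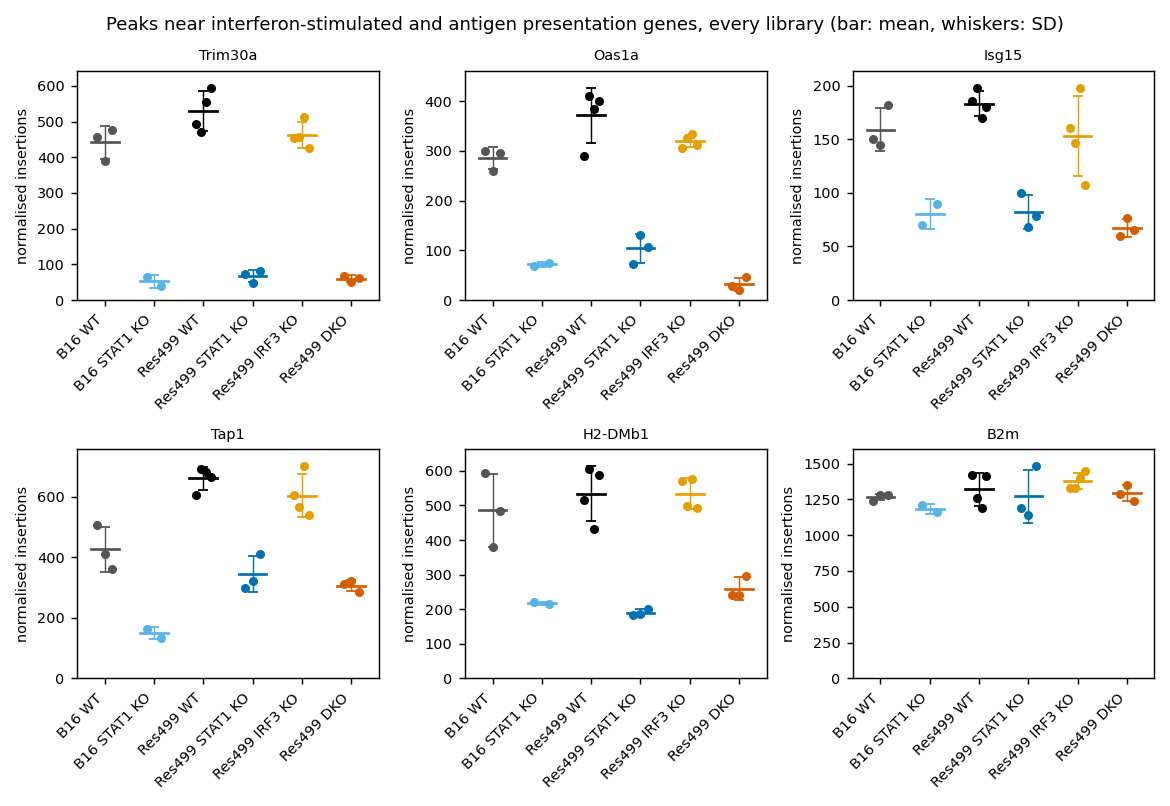
Normalised Tn5 insertions (vertical axes) per library, in the 6 groups named on the horizontal axes, for peaks at interferon-stimulated and antigen presentation genes; points are libraries, horizontal bars are group means and whiskers are SDs. The Oas1a peak stood at 371 in Res499 WT, 104 in Res499 STAT1 KO and 31.2 in DKO, and at 285 in B16 WT against 71.5 in B16 STAT1 KO.

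In B16, STAT1 KO against WT showed losses at interferon-stimulated and antigen presentation genes. Trim30a fell to 52.5 ± 18.8 from 441 ± 45.4 (8.41-fold, adjusted p = 1.6e-18) and Ifi47 to 23.4 ± 9.56 from 283 ± 127 (12.1-fold). The antiviral genes Oas1h (chromosome 5, 120870365 to 120871114) and Oas1g (chromosome 5, 120887275 to 120888024) were 3.7-fold and 3.76-fold lower, and a peak 1.3 kb from Rph3a was 3.44-fold lower. Of the 181 peaks of interferon-stimulated genes 48, at 31 genes, were lower and 133 did not pass (72 lower and 1 higher when adjusted over the list alone). The test of the list gave adjusted p = 1.3e-21, and adjusted p = 0.00638 with an estimated correlation. Of the 11 fixed genes, 6 had a lower best peak, among them Oas1a (3.99-fold, adjusted p = 1.9e-10), Ifit3 (2.54-fold, adjusted p = 6.9e-06) and Tap1 (2.87-fold, adjusted p = 1.9e-09). Of the others, Irf1 (adjusted p = 0.0223), Irf9 (0.0289) and Isg15 (0.00283) lost their calls without STAT1 KO replicate 1 (0.743, 0.286 and 0.259). Irf1 also lost it without B16 WT replicate 1 (0.0875) or 4 (0.0726). Irf9 also lost it without B16 WT replicate 1 (0.0701), 2 (0.0699) or 4 (0.0877), without STAT1 KO replicate 4 (0.0757) and with median centring (0.053). Cd274 stood at 61.1 ± 23 against 95.2 ± 7.72 (adjusted p = 0.123), and passed without STAT1 KO replicate 4 (0.0252). Of 39 MHC class II peaks 9 were lower (10 when adjusted over the list alone; adjusted p = 9.4e-08, but adjusted p = 0.133 with an estimated correlation), led by H2-Ab1 (3.46-fold), H2-DMb1 (2.24-fold) and H2-Eb1 (2.34-fold). Of 43 MHC class I peaks 7 were lower (8 lower and 1 higher when adjusted over the list alone; adjusted p = 0.0014, but adjusted p = 0.17 with an estimated correlation and 0.238 without STAT1 KO replicate 4), led by Tap2 (4.73-fold), Tap1 and the immunoproteasome gene Psmb9 (1.55-fold).

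Other gene groups also differed in B16 STAT1 KO. Of 250 peaks of dedifferentiated melanoma and neural crest genes, 16 were lower and 4 higher (33 and 7 when adjusted over the list alone; adjusted p = 9.6e-04, and adjusted p = 0.0309 with an estimated correlation), and the call was lost with regional shifts divided out (0.26) and with gene-end peaks (0.246). Of 194 hypoxia and glycolysis peaks, 20 were lower and 3 higher (25 and 3 when adjusted over the list alone). The list as a whole had adjusted p = 0.00651, but adjusted p = 0.194 with an estimated correlation, 0.246 with gene-end peaks and 0.31 without STAT1 KO replicate 4. Of 102 housekeeping peaks, 11 were lower and 1 higher (15 and 1 when adjusted over the list alone). The list test gave adjusted p = 0.00651, but adjusted p = 0.17 with an estimated correlation, 0.189 with gene-end peaks and 0.0511 without STAT1 KO replicate 4. Of 64 macrophage and myeloid marker peaks, 7 were higher and 57 did not pass (8 higher when adjusted over the list alone). Its list test gave adjusted p = 1.9e-04, but adjusted p = 0.124 with an estimated correlation and 0.189 with gene-end peaks. Leading peaks were near Ccn1, a secreted matrix protein (1.66-fold lower), near Tead1, a Hippo pathway factor (1.57-fold lower), inside Ero1a, an oxidoreductase of the endoplasmic reticulum (2.19-fold lower), and inside Gpi1, a glycolytic enzyme (2.42-fold lower). A peak 8.2 kb from Fcgr3, an Fc receptor gene of myeloid cells, stood at 925 ± 184 against 578 ± 55.5 (1.6-fold higher). The largest gains were inside Rabepk (429 ± 66 against 151 ± 56.1, 2.83-fold), Prr15l (2.31-fold) and Ciapin1 (3.36-fold), on chromosome 3 with no gene within 50 kb (52663097 to 52663846, 2.66-fold), and at the end of Lurap1l (2.06-fold). Without replicate 1 the adjusted p was 0.398 for Ccn1, 0.21 for Tead1 and 0.38 for Fcgr3.

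In B16 STAT1 KO 3916 peaks differed from WT, 1289 higher and 2627 lower, with 115 at least 2-fold higher and 476 at least 2-fold lower. This count rested on STAT1 KO replicate 1, since 185 peaks passed without it and 9937 without replicate 4, where a lone library is assumed to vary like the other groups. It was 2253 without B16 WT replicate 1 and 1569 without B16 WT replicate 4.

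The effect of STAT1 loss was then compared between the lines. Both STAT1 KO comparisons shared 521 lower peaks and 296 higher peaks, while 81 were opposite (independent lists would share 101.8 and 65.1), and the differences correlated at r = 0.31 across peaks, which are not independent replicates. Without B16 STAT1 KO replicate 1, 98 lower and 9 higher peaks were shared. The difference of effects passed at 1312 peaks, 764 positive (58.2%, and 46.1% with quantile normalisation) and 548 negative. For interferon-stimulated genes it passed at 4 of 181 peaks (3 positive and 1 negative; list adjusted p = 0.985). At MHC class II genes 1 of 39 peaks had a negative difference (adjusted p = 0.00221, but adjusted p = 0.534 with an estimated correlation and 0.414 with gene-end peaks). The fall at H2-Aa was larger in Res499 (difference of effects -0.51, adjusted p = 0.00218), as was the fall at Ifih1 (-0.46, adjusted p = 0.0144), and the fall at Ifit3 was smaller (0.42, adjusted p = 0.0346). Dedifferentiated melanoma and neural crest (7 positive and 1 negative of 250, adjusted p = 0.028), hypoxia (6 positive of 194, adjusted p = 0.00395) and housekeeping peaks (3 positive and 1 negative of 102, adjusted p = 0.00395) had positive differences, each at adjusted p = 0.29 with an estimated correlation. The first of these lost its call with regional shifts divided out (0.486), with 1 mean per gene (0.0779), and without B16 WT replicate 4 (0.0853), B16 STAT1 KO replicate 1 (0.389) or Res499 STAT1 KO replicate 2 (0.0623), and the hypoxia list without B16 STAT1 KO replicate 4 (0.126). The count of 1312 was 721, 757 and 723 without B16 WT replicate 1, 2 and 4, 226 and 3632 without B16 STAT1 KO replicate 1 and 4, and 3025, 736 and 591 without Res499 STAT1 KO replicate 1, 2 and 4.

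Res499 and B16 were also compared with STAT1 lost in both. The A830018L16Rik peak stood at 212 ± 11.2 in Res499 STAT1 KO and 33.5 ± 1.71 in B16 STAT1 KO, and the Phyhipl peak at 436 ± 34.6 and 34.4 ± 3. Of the 181 peaks of interferon-stimulated genes, 21 were higher in Res499 STAT1 KO and 7 lower (adjusted p = 0.544), and of 43 MHC class I peaks 6 were higher (adjusted p = 0.218; 0.00793 without B16 STAT1 KO replicate 1 and 0.045 with regional shifts divided out). In all 11977 peaks differed, 7127 higher and 4850 lower. The count was 5557 without B16 STAT1 KO replicate 1, and 7494 with only these groups in the fit. With gene-end peaks alone, the adjusted p of the interferon-stimulated list was 0.0401.

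IRF3 KO was compared with WT in Res499. The largest loss lay at an end of Mitf, the master transcription factor of melanocytes (chromosome 6, 98020860 to 98021609), where 173 ± 24.2 stood against 508 ± 68.6, a 2.94-fold lower level (-0.86 ± 0.08, adjusted p = 4.9e-11). Peaks inside Gns, a lysosomal sulfatase gene (3.8-fold lower), inside Copg1, a vesicle coat gene (2.18-fold), inside Foxn3 (2.41-fold) and at the end of Ccser1 (3.12-fold) followed. Not all of these losses were particular to IRF3 KO. The Mitf peak stood at 187, 168 and 228 in Res499 STAT1 KO and 388, 275 and 207 in DKO, against 431 to 597 in WT. The Gns peak stood at 108, 96.7 and 78.6 in STAT1 KO and 59.7, 51.5 and 71.9 in DKO, against 195 to 257. At Copg1, Foxn3 and Ccser1, STAT1 KO libraries overlapped WT and DKO libraries stood below it. Of the 5 largest gains 4 had no gene within 50 kb, such as chromosome 4, 72946402 to 72947151 (263 ± 8.38 against 87.2 ± 17.6, 3.01-fold higher), and the other lay inside Trpm1, a melanocyte cation channel gene (1360 ± 142 against 755 ± 133, 1.8-fold).

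Peaks of interferon-stimulated genes mostly did not pass in IRF3 KO, with 2 higher and 6 lower of 181 (list adjusted p = 0.313). Of the 11 fixed genes 1 had a best peak that passed, Cd274, at 92.3 ± 15.6 against 147 ± 24.6 (1.59-fold lower, adjusted p = 0.0068), and without Res499 WT replicate 2 its adjusted p was 0.0531. An Irf1 peak (319 ± 51.6 against 409 ± 72.4, adjusted p = 0.0639) passed without Res499 WT replicate 1 (0.0207) or IRF3 KO replicate 2 (0.0463), with quantile normalisation (0.0395) and with only these groups in the fit (0.0197). MHC class I peaks had 2 higher of 43 (adjusted p = 0.342), and the MHC class II list had adjusted p = 0.904. Of 77 fibroblast marker peaks 7 were lower and 70 did not pass (8 lower when adjusted over the list alone). Camera gave this list adjusted p = 0.0169, but adjusted p = 0.443 with an estimated correlation, 0.101 with quantile normalisation, 0.433 with regional shifts divided out, 0.869 with gene-end peaks and 0.0603 without Res499 WT replicate 3. They included peaks inside Pdgfra, a growth factor receptor gene (2.15-fold lower), and the collagen gene Col6a3 (1.61-fold lower). IRF3 KO had 5361 changed peaks, 2432 higher and 2929 lower, with 41 at least 2-fold higher and 236 at least 2-fold lower. The higher share was 45.4%, and 56% with median centring. The count was 3339 without Res499 WT replicate 3, and 2801 and 3415 without IRF3 KO replicate 3 and 4. Titles of the IRF3 KO and DKO libraries lack an ending that the other titles share, so a batch, if there was one, cannot be told apart from these genotypes.

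DKO was compared with WT in Res499. The peak inside Copg1 fell to 96.5 ± 8.66 from 838 ± 50.5 (8.69-fold, -1.71 ± 0.07, adjusted p = 1.8e-27). Peaks at Oas1g (19.8 ± 2.88 against 403 ± 29, 20.3-fold), Ifi47 (24.9 ± 1.77 against 434 ± 33.4, 17.4-fold), Oas1h (8.69-fold) and near Rph3a (8.83-fold) were lower. The largest gains were inside Il33, the gene of an alarmin cytokine (chromosome 19, 29947977 to 29948726, 588 ± 32.3 against 76.9 ± 18.9, 7.65-fold higher), inside Tafa5 (1840 ± 34.7 against 511 ± 71.6, 3.59-fold), on chromosome 1 far from any gene (102170463 to 102171212, 8.73-fold), 25.6 kb from Slc25a33, a mitochondrial carrier gene (7.45-fold), and inside Rora, a nuclear receptor gene (10.6-fold).

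Of 181 peaks of interferon-stimulated genes, 93, at 49 genes, were lower in DKO and 4 higher (100 and 5 when adjusted over the list alone). For the list, adjusted p was 8.9e-13, and adjusted p = 0.0514 with an estimated correlation. Of the 11 fixed genes 10 had a lower best peak, including Oas1a (31.2 ± 13.6 against 371 ± 55.2, 11.9-fold, adjusted p = 4.5e-23), Irf7 (2.23-fold, adjusted p = 1.6e-12), Isg15 (2.73-fold, adjusted p = 2.8e-09) and Cd274 (63.8 ± 10.8 against 147 ± 24.6, 2.3-fold, adjusted p = 1.3e-06). B2m stood at 1290 ± 57.8 against 1320 ± 117 (adjusted p = 0.834). Of these, the Stat1 peak inside the gene (adjusted p = 0.0212) lost its call without Res499 WT replicate 1 (0.0576) or 3 (0.0554), without DKO replicate 1 (0.0941) or 3 (0.1) and with regional shifts divided out (0.234). Mx1 (1.22-fold lower, adjusted p = 0.0375) lost it without Res499 WT replicate 2 (0.0583), 3 (0.0901) or 4 (0.105), without DKO replicate 1 (0.148) or 4 (0.102) and with median centring (0.0584). With DKO replicates 1 and 3 taken as 1 library, neither passed (0.0962 and 0.0689). Other peaks of these genes need not be lower. An Irf1 peak (chromosome 11, 53795032 to 53795781) stood at 859, 842 and 787 in DKO against 694 to 815 in WT. An Mx1 peak (chromosome 16, 97466396 to 97467145) stood at 99.7, 92.7 and 96.3 against 73.2 to 103. Over all peaks of the genome, 35.5% changed in DKO. MHC class I peaks had 13 of 43 lower and 3 higher (14 and 4 when adjusted over the list alone; adjusted p = 0.0194, but adjusted p = 0.59 with an estimated correlation, 0.168 with gene-end peaks, 0.164 with 1 mean per gene and 0.0601 without DKO replicate 4), led by Tap1 (2.16-fold), H2-Q4 (2.06-fold) and Tap2 (2.57-fold). MHC class II peaks had 15 of 39 lower and 1 higher (16 and 1 when adjusted over the list alone). The test of the list gave adjusted p = 0.00182, but adjusted p = 0.613 with an estimated correlation and 0.0858 with 1 mean per gene.

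Peaks of melanocyte pigmentation genes were higher in DKO at 88 of 294 and lower at 45 (91 and 48 when adjusted over the list alone). The list as a whole had adjusted p = 0.0441, but adjusted p = 0.731 with an estimated correlation, 0.196 with quantile normalisation, 0.682 with gene-end peaks and 0.164 with 1 mean per gene. Without Res499 WT replicate 1, 3 or 4 this adjusted p was 0.0522, 0.0597 or 0.0904, and without DKO replicate 1 or 3 it was 0.126 or 0.258. The leading peaks were at Trpm1 (438 ± 82.4 against 92.9 ± 10.1, 4.72-fold higher), the melanosome exchanger gene Slc24a5 (2.32-fold) and Rab38, which traffics pigment enzymes (2.76-fold). Of 250 peaks of dedifferentiated melanoma and neural crest genes, 79 were lower and 28 higher (82 and 30 when adjusted over the list alone). The list test gave adjusted p = 0.0198, but adjusted p = 0.15 with an estimated correlation, 0.892 with regional shifts divided out, 0.706 with gene-end peaks, 0.423 with 1 mean per gene and 0.0601 without DKO replicate 4. Peaks inside Sox5 (93.7 ± 29.5 against 404 ± 67.4, 4.31-fold lower) and Sox6 (3.15-fold lower), both transcription factor genes, and near Ccn1 (2.14-fold lower) led it. In all, 31130 peaks (35.5%) changed, 14546 higher and 16584 lower, with 1408 at least 2-fold higher and 4293 at least 2-fold lower. Of these, 21878 were called in the same direction once regional shifts were divided out.

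**Figure D3:**
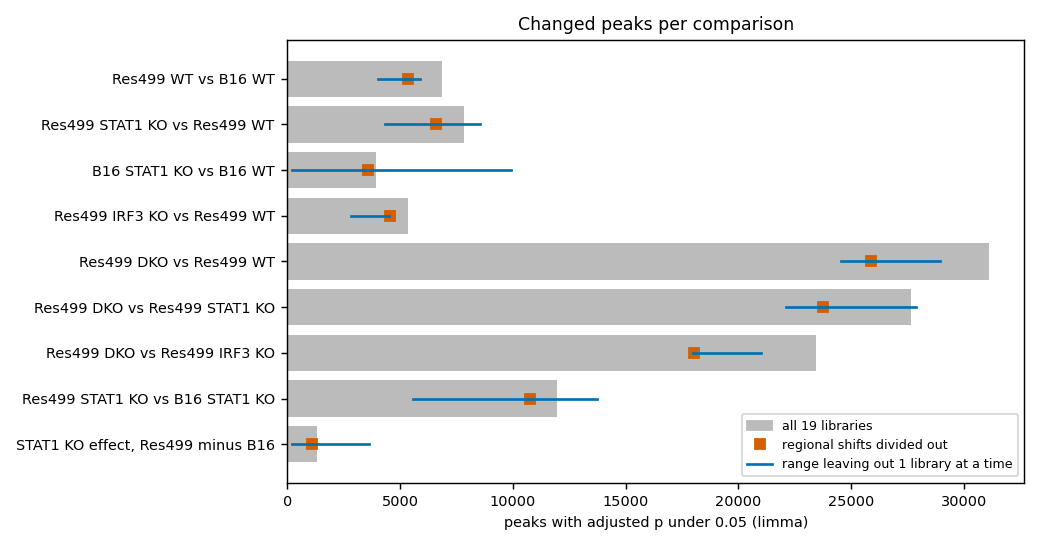
Number of peaks changed (horizontal axis) in each comparison (vertical axis), at a limma adjusted p under 0.05 over 87697 peaks; grey bars from 0 are counts over all 19 libraries, orange squares the counts with regional shifts divided out, and blue lines the range when libraries were left out one at a time. DKO against Res499 WT had 31130 changed peaks and IRF3 KO against Res499 WT had 5361.

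DKO was then set against each single knockout. Against IRF3 KO, 87 of the 181 peaks of interferon-stimulated genes, at 51 genes, were lower in DKO and 4 higher (91 and 5 when adjusted over the list alone). Its list test gave adjusted p = 3.0e-14, and adjusted p = 0.0345 with an estimated correlation. MHC class I (15 of 43 lower and 2 higher, adjusted p = 1.5e-04, but adjusted p = 0.147 with an estimated correlation) and MHC class II peaks (15 of 39 lower, adjusted p = 4.3e-05, but adjusted p = 0.326 with an estimated correlation) were lower too. Pigmentation peaks were higher at 64 of 294 and lower at 29 (adjusted p = 0.00565, but adjusted p = 0.431 with an estimated correlation, 0.226 with gene-end peaks, 0.221 with 1 mean per gene and 0.0713 without DKO replicate 3). Dedifferentiated melanoma and neural crest peaks were lower at 61 of 250 and higher at 27 (adjusted p = 0.0222, but adjusted p = 0.147 with an estimated correlation, 0.995 with regional shifts divided out, 0.624 with gene-end peaks, 0.471 with 1 mean per gene and 0.0588 without DKO replicate 4). Against STAT1 KO, 38 interferon-stimulated peaks were lower and 18 higher (adjusted p = 0.401, and 0.0398 with gene-end peaks). MHC class II peaks were higher at 7 of 39 (adjusted p = 0.0289, but adjusted p = 0.73 with an estimated correlation, 0.138 with regional shifts divided out, 0.124 with gene-end peaks, 0.152 with 1 mean per gene, 0.064 and 0.0649 without STAT1 KO replicate 2 and 4, and 0.121 without DKO replicate 4). DKO differed from STAT1 KO at 27670 peaks (12050 higher and 15620 lower) and from IRF3 KO at 23433 (10237 higher and 13196 lower).

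To ask whether the knockouts returned the chromatin of Res499 towards that of B16, 2 of the 4 Res499 WT libraries defined the peaks gained or lost against B16 and the other 2 served as control, in all 6 splits. Of the 2135 to 2511 gained peaks, 76.4% (75.1 to 78 over the splits) moved in the direction of B16 in DKO, 71.9% (68.2 to 76.1) in IRF3 KO and 47.8% (46.9 to 48.4) in STAT1 KO. These shares count direction only, so peaks that moved past the B16 level are included. A simulated unchanged group gave 49.5%, a value set in advance, since that group and its control were drawn around the same mean. Its peaks varied independently, so it does not measure the spread that shifts shared by many peaks give. A median 41.1% of the difference from B16 was kept in DKO, 78.5% in IRF3 KO and 102.7% in STAT1 KO. The highest adjusted p over the splits for movement of the gained peaks in one direction (fry of limma) was 3.4e-08 in DKO, 5.8e-05 in IRF3 KO and 0.816 in STAT1 KO. Among gained peaks at least 2-fold higher, the STAT1 KO share turned to 57% (55.5 to 58.2), with 93.3% of the difference kept and a highest adjusted p of 0.304. Single gained peaks differed, since the Kctd3 peak stood at 22.3 ± 18.5 in DKO and 129 ± 29.1 in STAT1 KO against 287 ± 43.5 in WT, while the Phyhipl peak stood at 83.2 ± 33.6, 436 ± 34.6 and 312 ± 41.7. Of the 1238 to 2211 lost peaks, 52.4% (42 to 61.9) moved in the direction of B16 in DKO, 64.8% (52.1 to 73.8) in IRF3 KO and 38.2% (32.1 to 43.7) in STAT1 KO, with highest adjusted p-values (fry) of 0.499, 0.499 and 0.122 and lowest ones of 1.6e-06, 1.6e-06 and 0.0107. The simulated group gave 49.6%, with the same limit. With regional shifts divided out, the STAT1 KO share was 34.5% and its highest adjusted p over the splits was 0.023.

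The Res499 knockouts also shared changed peaks, though all used the same WT libraries. STAT1 KO and DKO shared 1672 lower and 1737 higher peaks, where independent lists would share 642.4 and 734.3, and 823 were opposite. IRF3 KO and DKO shared 2115 lower and 1463 higher (independent lists 553.9 and 403.4), and 208 were opposite. Titles of both these groups lack the ending of the WT titles. A batch that follows the titles cannot be told apart from a shared effect of these genotypes, and splitting the WT libraries does not remove it. STAT1 KO and IRF3 KO shared 288 lower and 412 higher (113.5 and 122.8), and 380 were opposite. Unchanged groups simulated against the same controls shared 0 peaks by limma in each pair. Few peaks can pass in such groups, so this does not show how much overlap shared controls add between lists of changed peaks. With the WT libraries split between the knockouts, 1321 peaks went the same way and 389 opposite for STAT1 KO and DKO, 1290 and 84 for IRF3 KO and DKO, and 144 and 162 for STAT1 KO and IRF3 KO. The covariance of the differences was 0.00727, 0.0106 and 0.00251 for these 3 pairs, where shared controls alone gave 0.00192.

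Large chromosomal regions shifted in DKO, though not in DKO alone. The median log2 ratio to Res499 WT was -0.30 over chromosome 3, -0.21 over chromosome 7, -0.20 over chromosome 1 and -0.19 over chromosome 8, and it was 0.22 over chromosome 15 and 0.14 over chromosome 9. These are medians over each chromosome, and not all parts of a chromosome shifted alike. In bins of 10 Mb, the ratio was 0.01 in the chromosome 1 bin that starts at 130 Mb and -0.70 in the next (50 peaks). It was 0.01 in the chromosome 8 bin that starts at 120 Mb. On chromosome 9 it was 0.27, 0.41 and 0.4 over the first 3 bins and 0.01 to 0.15 over the others. Over the 11 peaks of chromosome Y, the median log2 ratio of Res499 WT to B16 WT was -0.85 and that of DKO to Res499 WT 0.61, which is the largest of any chromosome. On chromosome 12, bins from 30, 40 and 50 Mb were higher in Res499 WT than in B16 WT (0.22, 0.35 and 0.34) and lower in DKO than in Res499 WT (-0.25, -0.30 and -0.30). From 90 Mb on, chromosome 10 was higher than in B16 WT by 0.27 in Res499 WT and 0.32 in DKO, over 1453 peaks. Regions also shifted in the single knockouts. Against Res499 WT, the chromosome 1 bins from 20 to 100 Mb lay at -0.23 to -0.12 in IRF3 KO and at -0.46 to -0.21 in DKO. In Res499 STAT1 KO the median was 0.14 over chromosome 15. The chromosome 8 bins from 100, 110 and 120 Mb lay at 0.18, 0.24 and 0.21 in STAT1 KO and at -0.04, -0.14 and 0.01 in DKO.

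**Figure D4:**
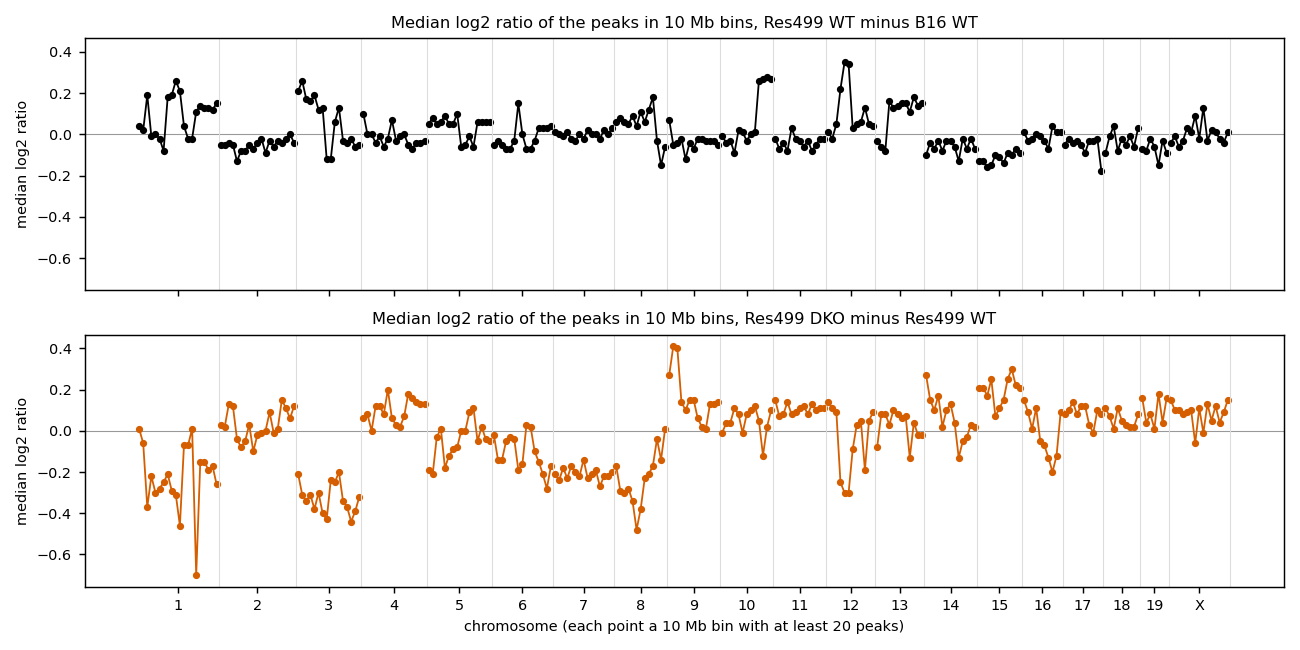
Median log2 ratio of normalised insertions (vertical axis) in 10 Mb bins along the chromosomes (horizontal axis); points are bins with at least 20 peaks, the upper panel is Res499 WT against B16 WT and the lower panel DKO against Res499 WT. In DKO against Res499 WT, chromosome 3 lay at a median of -0.30 and chromosome 15 at 0.22.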

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

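The tests of library-to-library variation, of gained peaks in splits, of B16 cells and mixtures in DKO and IRF3 KO, and of other cell types in B16 STAT1 KO were chosen only after the result was seen, and those of DNA copies, depth and regional shifts only after the data were seen, while other splits of the libraries were planned.

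Other splits of the same libraries asked whether a random division of the libraries gives as many changed peaks, and in each of the 6 comparisons with at least 3 libraries per group 1 split, the real one, gave the most. Comparisons with B16 STAT1 KO were not split. Among 35 splits, a random division is argued against, at a share under 0.05, for Res499 against B16 (6847 peaks, highest other split 1936), Res499 STAT1 KO (7824, highest other 2046) and IRF3 KO (5361, highest other 4). The same holds for DKO against WT (31130, highest other 15297) and DKO against IRF3 KO (23433, highest other 8533). These shares were not adjusted over the comparisons and cannot be smaller with so few splits, so chance is not excluded. For DKO against STAT1 KO the 10 splits are too few for a share under 0.05 (27670 peaks, highest other 0 by limma).

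Much of chromosomes 3, 7, 1 and 8 was lower in DKO than in Res499 WT (median log2 ratios over each chromosome -0.30, -0.21, -0.20 and -0.19) and chromosomes 15 and 9 higher (0.22 and 0.14). Variation between libraries is argued against, since the shift was at least 11.46 times the largest deviation of any library from its group mean on chromosomes 3 and 9, at least 6.67 times on chromosomes 1 and 8, 5.81 times on chromosome 7 and 7.26 times on chromosome 15. A change in DNA copies of whole regions may contribute, since over 222 bins the median ratio of gene-end peaks followed that of distal peaks with a slope of 0.82 (95% interval 0.77 to 0.86). Copies alone would move both kinds of peak alike, a slope of 1, which lies outside this interval, though noise in the distal medians also lowers a slope. Any other shift of whole regions would move both kinds too, so the slope does not single out copies. Whether a change in copies came with the genotype or with a selected clone was not tested, and a batch that follows the titles cannot be told apart from the genotype.

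Peaks gained in Res499 over B16, chosen on 2 Res499 WT libraries and measured against the other 2, fell, in the direction of B16 levels, in DKO (76.4% of them) and in IRF3 KO (71.9%). For DKO, B16 cells are argued against because the libraries kept a fraction of at least 0.71 of the difference from B16 at peaks lost in Res499, and a mixture of both lines in 1 proportion because that fraction exceeded the one kept by gained peaks (0.25 to 0.4) by at least 0.4 in every library and split (SD 0.02 to 0.05), although among peaks changed at least 2-fold this difference (at least 0.4, SD 0.22 to 0.29) was over 3 SD in 0 of the 6 splits and regions went both ways, with a fraction of 1.1 to 1.26 of the gain of Res499 kept on chromosome 10 from 90 Mb on but that in the chromosome 12 bin that starts at 40 Mb (0.35 in Res499, -0.30 in DKO) largely lost. DNA copies of whole regions as the whole cause are argued against because a share of 0.9 (0.91 to 0.92 in the splits) of the median fall of 686 peaks gained at least 2-fold remained with regional shifts divided out (-0.3 before, -0.27 after). Copy changes of stretches much shorter than 10 Mb would hardly move a regional median, so this test cannot decide on them. For IRF3 KO, a mixture as the whole cause is argued against because those peaks scattered around 1 kept fraction 8.66 times (5.57 to 8.68 in the splits) as much as the spread between libraries gives, while a mixture as part of it cannot be told apart, since lost peaks kept a mean of 0.12 more than gained ones (SD 0.04 to 0.07), by no more than 3 SD in any split. The IRF3 KO libraries kept a fraction of 0.74 to 0.93 of the Res499 gain on chromosome 10 from 90 Mb and 0.75 to 0.79 of that at the 686 peaks, which also leaves a partial mixture open. An effect of the genotypes on these peaks is the biological hypothesis, open in IRF3 KO beside a partial mixture. In both genotypes it is open beside copy changes of short stretches, which were not tested, and beside a batch, which cannot be told apart from the genotype.

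The count for B16 STAT1 KO rested on replicate 1, with 185 peaks without it and 9937 without replicate 4. Depth is argued against, since the counts still differed 61.6 times with libraries thinned to 1 total, and regional shifts are argued against, since they differed 52.6 times with those divided out. Cells of another type in replicate 1 may contribute, since the median log2 ratio of replicate 1 to replicate 4 reached percentile 100 of 10000 random lists for myeloid (0.16) and endothelial markers (0.2), 99 for T and NK cell markers (0.1), 94.1 for B cell markers (0.12) and 67.8 for fibroblast markers (-0.01), although a sort for tumor cells would remove such cells. This ratio cannot tell a rise in replicate 1 from a fall in replicate 4. Random lists drew their peaks singly, while marker lists hold several peaks per gene, so these percentiles may be too extreme. On the deposited scale, relative to the B16 WT mean, endothelial peaks averaged 0.013 in replicate 1 and -0.04 in replicate 4. Myeloid peaks averaged 0.121 and 0.048, T and NK cell peaks 0.035 and 0.012, B cell peaks 0.045 and -0.019, and fibroblast peaks -0.012 and -0.005. Higher marker averages were not particular to this library. Myeloid peaks averaged 0.102, 0.064 and 0.012 in Res499 STAT1 KO replicates 1, 2 and 4, 0.073 in DKO replicate 4 and 0.014 to 0.033 in Res499 WT. B cell peaks averaged 0.133 in DKO replicate 4 and 0.02 to 0.053 in Res499 WT. Of the myeloid peaks, that near Fcgr3 stood at 925 ± 184 in B16 STAT1 KO against 578 ± 55.5 in B16 WT, that near Fcgr1 at 334 ± 105 against 210 ± 15.3 and that near Aif1 at 343 ± 28.1 against 244 ± 17.4 (B16 WT thus had insertions there too), and 0 of the 30 myeloid, 18 endothelial, 32 T and NK cell and 11 B cell genes and 3 of the 18 fibroblast genes stand in another list. A biological difference between these samples was not tested.

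In 8 of 224 groups of 4 libraries 1 library stood far from the others, where chance gives about 1 in 20 groups. The gap, as a share of the range, was 0.94 for the Tap2 peak (Res499 WT replicate 4, 340 normalised insertions, others 269 to 273). It was 0.96 for the Col6a3 peak (Res499 WT replicate 3, 221, others 179 to 181) and 0.84 for the Ccser1 peak (Res499 WT replicate 1, 161, others 222 to 234). In IRF3 KO it was 0.83 for Fcgr1 (replicate 4, 302, others 250 to 259), 0.85 for Polr2a (replicate 1, 122, others 96.1 to 100) and 0.86 for Slc25a33 (replicate 4, 43.8, others 65.1 to 68.5). For the mean deposited value of a list, it was 0.9 for NF-kB genes (IRF3 KO replicate 4, 8.96, others 8.98) and 0.94 for MHC class I (Res499 WT replicate 2, 9.43, others 9.39).

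The effect of STAT1 loss differed between the lines, by the limma test of the difference of effects (Res499 minus B16), at 19 named peaks. Differences were positive at Klhl29 (0.91), Tafa5 (0.63), Nr3c2 (0.63), Gpi1 (0.56), Tcf7l1 (0.5), Ptx3 (0.43), Ifit3 (0.42), Ccn1 (0.42), Polr2a (0.41) and Tead1 (0.36). They were negative at Ttc39b (-1.5), Rabepk (-1.06), Ciapin1 (-0.7), Prr15l (-0.69), a chromosome 3 peak with no gene within 50 kb (-0.55), Fcgr3 (-0.54), H2-Aa (-0.51), Lurap1l (-0.47) and Ifih1 (-0.46). Peaks named for their change in one line were selected on libraries that also enter this test. Among lists, MHC class II (adjusted p = 0.00221), dedifferentiated melanoma and neural crest (0.028), hypoxia and glycolysis (0.00395) and housekeeping genes (0.00395) differed, and none of these 4 calls held with an estimated correlation (0.534 for the first and 0.29 for the others).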

How the results depend on the processing

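Regional shifts divided out, voom, thinned counts, 1 library for DKO replicates 1 and 3 and leaving out libraries in the list tests were chosen only after the data were seen. No named peak or list reversed in a test. Among shares of lost peaks, that of DKO reversed in 1 split. Of the alternatives for named peaks, 1820 kept a call, 65 lost it, 405 stayed without one and 8 gained one, and for lists called at the preset correlation, other than interferon-stimulated and MHC class I genes, 218 kept it and 65 lost it. Such lists that had not been called gained a call 16 times under other settings and 15 times with a library left out. Where a value below moved, the cause was not tested, except that leaving out libraries or peaks leaves fewer to test. Changed peaks with libraries left out ranged from 4017 to 5902 (Res499 against B16), 4315 to 8560 (Res499 STAT1 KO), 185 to 9937 (B16 STAT1 KO), 2801 to 4518 (IRF3 KO), 24562 to 28935 (DKO), 22126 to 27877 (DKO against STAT1 KO), 17985 to 20998 (DKO against IRF3 KO), 5557 to 13717 (STAT1 KO in both lines) and 226 to 3632 (difference of effects). With only the compared groups, STAT1 KO in both lines had 7494.

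For interferon-stimulated genes, adjusted p with libraries left out ranged from 0.205 to 0.999 (Res499 against B16), 1.0e-26 to 1.1e-18 (Res499 STAT1 KO), 8.2e-27 to 2.3e-12 (B16 STAT1 KO), 0.0534 to 0.813 (IRF3 KO), 2.4e-13 to 1.7e-11 (DKO), 0.37 to 0.501 (DKO against STAT1 KO), 1.6e-15 to 1.8e-12 (DKO against IRF3 KO), 0.48 to 0.958 (STAT1 KO in both lines) and 0.686 to 0.988 (difference of effects). It was 0.0514 in DKO with an estimated correlation, and with gene-end peaks 0.0398 in DKO against STAT1 KO and 0.0401 for STAT1 KO in both lines. For MHC class I, in the same order, the ranges were 0.0111 to 0.234, 3.6e-04 to 0.0773, 1.1e-07 to 0.238, 0.228 to 0.725, 0.00814 to 0.0601, 0.404 to 0.86, 4.9e-05 to 0.00165, 0.00793 to 0.48 and 0.281 to 0.978. In Res499 against B16 it was 0.0182 with quantile normalisation and 0.0473 with voom. With an estimated correlation it was 0.325 (Res499 STAT1 KO), 0.17 (B16 STAT1 KO), 0.59 (DKO) and 0.147 (DKO against IRF3 KO). With gene-end peaks it was 0.126 (Res499 STAT1 KO) and 0.168 (DKO), with 1 mean per gene 0.164 (DKO), and with regional shifts divided out 0.045 (STAT1 KO in both lines). Of the 28 list calls, 5 were kept with an estimated correlation, 26 with quantile normalisation (3 others gained), 14 with gene-end peaks (9 gained), 19 with 1 mean per gene (3 gained), 22 with regional shifts divided out (5 gained) and 28 with voom (1 gained). Of the 11 calls in comparisons with B16 STAT1 KO, 10 were kept without its replicate 1 and 1 other was gained. Among the gains by camera, with gene-end peaks, were hypoxia genes in Res499 STAT1 KO (0.506 to 2.1e-05, higher), IRF3 KO (0.313 to 0.0408, higher), DKO against STAT1 KO (0.401 to 0.0153, lower) and STAT1 KO in both lines (0.306 to 0.0188, higher in Res499), and nucleic acid sensing in DKO against IRF3 KO (0.146 to 0.0012, lower). Hypoxia genes in DKO against IRF3 KO (0.0744, lower) passed with quantile normalisation (0.0255), 1 mean per gene (0.0211) and regional shifts divided out (0.0418). They also passed without IRF3 KO replicate 4 (0.043) or DKO replicate 4 (0.0236). MHC class II in Res499 against B16 passed with regional shifts divided out (0.175 to 0.0398).

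Of lost peaks, the share that moved in the direction of B16 was 34.5% in STAT1 KO with regional shifts divided out, where movement away from B16 passed by fry in each of the 6 splits (highest adjusted p = 0.023). In single splits that passed it was 36.7, 37.8, 32.1 and 39.4% in STAT1 KO, 63.3, 66.2, 73.8, 65.3 and 68% in IRF3 KO, and 42 (reversed), 61.9, 53.2 and 55.1% in DKO, and in those that did not it was 43.7 and 39.3%, 52.1%, and 49.6 and 52.3%. Shared calls were 144, 1321 and 1290 with the controls split, and 208, 1345 and 1460 with all controls in both lists at an adjusted p under 0.01, for STAT1 KO with IRF3 KO, STAT1 KO with DKO and IRF3 KO with DKO.

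Replicate numbers did not pair the libraries, since 2 of 26 same-numbered pairs had a correlation of deviations over 0.1 (-0.31 to 0.21). With the replicate block, counts were 6276 (Res499 against B16), 2881 (B16 STAT1 KO), 5145 (IRF3 KO), 29661 (DKO) and 21968 (DKO against IRF3 KO), and all 19 list calls of these comparisons were kept. No paired analysis was possible because the column numbers of Res499 STAT1 KO differ from its titles, for comparisons with that group. GC correction, alone or with the block, and motif tests were not run, since no genome sequence was used here. Depth limits peaks near the floor of 2.02 to 4.1 normalised insertions.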

Other observations

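The X chromosome and the line-by-STAT1 tests below were chosen only after the result was seen. Some gene groups passed in none of the 9 comparisons with the preset correlation and all assigned peaks. Their lowest adjusted p was 0.122 for AP-1 and immediate early genes, growth factor response genes, in DKO against IRF3 KO (16 peaks higher and 46 lower of 156), 0.122 for B cell markers (5 higher of 24) and 0.146 for cell cycle genes (4 higher and 18 lower of 123), both in the same comparison. In Res499 STAT1 KO against WT it was 0.127 for endothelial markers (2 higher and 2 lower of 86), 0.184 for inhibitory ligands and other ligands of T cells (4 higher and 6 lower of 68) and 0.417 for NF-kB inflammatory genes (4 higher and 7 lower of 125). For mesenchymal and matrix genes it was 0.378 in Res499 against B16 (9 higher and 12 lower of 198). In Res499 STAT1 KO against WT, however, mesenchymal and matrix genes passed with gene-end peaks (1.7e-04, against 0.966 with all peaks) and inhibitory ligands with 1 mean per gene (0.0387).

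A hypothesis taken from the title of the series, that loss of STAT1 lowers interferon-stimulated genes more in Res499 than in B16, found no call in the test of the difference of effects (list adjusted p = 0.985), which does not show that the effects were equal.

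Peaks at least 2-fold higher in Res499 than in B16 lay on the X chromosome more often than other peaks, with 25 of 686 (3.6%) against 1.6% of all peaks (odds ratio 2.31, Fisher's exact test p = 2.1e-04). With regional shifts divided out, 24 of 668 lay there (odds ratio 2.28, Fisher's exact test p = 3.3e-04). Of the peaks at least 2-fold lower, 11 of 163 lay on X, a larger share than among the higher ones, which was not tested. The excess on X was thus not particular to the peaks gained in Res499. Neighbouring peaks are not independent, so these p-values are too small.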
